A study of Homo sapiens with 6 samples.

How the data were processed

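H1299 cells infected with 6 different adenoviruses were measured on 6 one-colour arrays, 1 array per virus. The infected groups are called Ad-LacZ, Ad-p53, Ad-p63a, Ad-p63g, Ad-p73a and Ad-p73b after the gene each virus carried. Per the labels' protocols, 100 ng of total RNA per culture was amplified and labelled with Cy3. All 6 arrays lay on 1 slide, with Ad-LacZ and Ad-p53 in slide row 1 and the other 4 arrays in slide row 2. Slide position and infection cannot be told apart with 1 array per group.

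The deposited scanner files hold spot intensity values that Agilent Feature Extraction 10.7 had background-subtracted and detrended within each array, per the file headers, with no normalization between arrays. Per the file headers, probe coordinates are on the human genome build hg19. The authors also deposited a table of log2 values for the same arrays. The submitters' processing notes name Agilent Feature Extraction and limma but not the steps, so the background correction and the normalization behind that table are not given in the sources used here. Its columns had nearly equal quantiles (medians of 5.85 to 5.87), and their slopes against log2 scanner signal lay between 0.966 and 1.02 over bright probes, so its scale was taken as log2. It was used as an alternative, with 0 columns belonging to other series.

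The main values were log2 processed signal minus each array's 75th percentile of it. Because 48.1% of probes on average were well above background, the percentile was taken over the 20721 probes well above background on all 6 arrays. Control spots and spots marked as outliers were left out, and no spot was saturated. Spots of 1 probe were averaged, and a probe counted as well above background when at least a share of 0.5 of its spots was. The 58717 spots left belonged to 50599 probes. The probe with the highest mean over the 6 arrays stood for a gene.

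Names came from RefSeq symbols of assembly GRCh38.p14, used for names only. Of the probes, 28174 matched by accession, 2618 by symbol and 620 by an older symbol, which gave 21355 genes, 7058 of them with 2 or more probes. The files call 8971 probes lincRNA probes, and these formed 6829 lincRNA features, 1 per XLOC locus. The remaining 10308 probes had neither kind of name and entered no comparison of genes or lincRNA features.

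No test was possible with 1 array per group, so a fixed rule of size was used. A gene or lincRNA feature counted as higher or lower when its log2 difference was at least 1 in size and its probe was well above background on both arrays. Where it was well above background on 1 array only, the other array's value was replaced by the higher of its own signal and the lowest signal well above background on that array. The resulting fold is a bound, written "at least", and the feature counted when that bound reached 2-fold. Features not well above background on either array were not considered.

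A set of 23 gene lists was written down, holding 408 members, of which 400 had a probe. They cover the transferred gene families, p53 targets in arrest, repair and feedback, in apoptosis, and in metabolism and autophagy, the G2/M and G1/S phases, and replication-dependent histones. Others cover keratinocyte and epithelial adhesion genes of the p63 program, multiciliated cell genes of the p73 program, the Notch pathway, interferon response, NF-kB and inflammatory genes, immediate early genes, the unfolded protein and integrated stress response, heat shock, and cholesterol synthesis. The last ones cover mesenchymal genes of the epithelial to mesenchymal transition (EMT), housekeeping genes, ribosomal proteins, known long noncoding RNAs, and markers of blood, of endothelium and fibroblasts, and of differentiated lung epithelium. Each list's median difference, over members well above background on at least 1 of the 2 arrays, was ranked among the medians of 10000 random lists of equal size matched on mean signal in 10 bins. The median used each member's own signal, also where it was not well above background, and the median with members at their bound is given too where it differs from this by over 1.5 times or in sign. The percentile is a description of these libraries, not of the conditions, and a median outside the central 95% was called apart. The list of the transferred genes was too short, below 4 members, to be ranked. Chance alone puts 5% of lists of independent genes apart.

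The genes named in the text follow a rule. It takes the transferred genes, up to 4 members per list with the largest differences past the size rule, the 5 highest and 5 lowest genes per comparison, the 3 highest and 3 lowest lincRNA features per infection, and genes higher in all 5 infections. The highest and lowest were ranked among features well above background on both arrays, since a bound has no rank. Some genes that the rule takes are not reported here. The groups, the size rule, the lists, the naming rule and 13 of the 19 processing alternatives were fixed before the data were examined. Those 13 were normexp background correction with an offset of 50, quantile normalization, median scaling, the authors' value table, detection on both arrays, on all 6 arrays or no detection filter, outlier spots kept, the mean over probes, thresholds of 1.5-fold and 4-fold, list members set at their bound, and a wider lincRNA class. Added after seeing the data were the 75th percentile over all probes, spike-in scaling, removal of the probe GC trend, leaving out features lit on Ad-LacZ alone, requiring all probes of a gene past the threshold, and leaving out spots in bright patches.

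A bright patch was found where, among the neighbours of a spot within a window of 5 by 5 spots, spots at least 1.5 (log2) above the median of the other 5 arrays were more frequent than a binomial tail of 0.0001 allows. This marked 804 spots (1.28%) on the Ad-LacZ array, 428 on Ad-p63g, 266 on Ad-p73a, 224 on Ad-p53, 139 on Ad-p63a and 3 on Ad-p73b. It is stated in the text where the spot behind a named gene lay in such a patch.

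Scaling moved the median difference of all genes by over 0.1 (log2) in some settings. Spike-in scaling, which rests on 7 probes for control RNAs added before labelling, moved it by -0.52 for Ad-p53, -0.32 for Ad-p63a, -0.49 for Ad-p63g, -0.26 for Ad-p73a and -0.58 for Ad-p73b against Ad-LacZ. It moved the difference of the p63 forms by -0.17 and that of the p73 forms by -0.32. For Ad-p53, median scaling moved it by -0.31, normexp by 0.18 and quantile normalization by -0.10, and median scaling moved Ad-p63a by -0.10. Differences in the text are relative to the array's 75th percentile unless another scaling or the authors' table is named, and a shift of the total RNA content of the cells would not be seen.

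Comparisons with Ad-LacZ share 1 array, so unchanged arrays were simulated 100 times. Noise came from probes spotted 10 times (standard deviation 0.113 on log2 scale) or, as an upper bound that also holds real differences, from the smallest variance between any 2 arrays (0.404, from Ad-p63a and Ad-LacZ). On simulated data for Ad-p53 against Ad-LacZ with the lower noise, over 14110 genes, the size rule called 96% of genes raised 2.5-fold and 92% of genes lowered 2.5-fold. At 8-fold it called 100% of raised and 84% of lowered genes, since lowered dim genes reach the background, and the tolerance set for this check was loosened after its first run for that reason. It called 0% of genes changed 1.5-fold and 0% of unchanged genes. With the upper noise, over 14080 genes, it called 7.81% of unchanged genes, and 28%, 74%, 80% and 94% of those changed 1.5-fold, 2.5-fold, 4-fold and 8-fold. The real arrays of Ad-p63a and Ad-LacZ, which gave this noise, had 2.08% of genes called, so the simulated noise called more genes than that comparison held. Simulated lists without a shift were called apart in 2.50% and 3.50% of cases, and lists shifted by 1 in 100%. These lists were random genes with independent noise, so they check the ranking only and not lists of genes that vary together. The computations used R 4.3.3 with limma 3.58.1 and version 1.17.8 of data.table, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.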

Results

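The experiment asked how members of the p53 family alter RNA levels, lincRNAs (long intergenic noncoding RNAs) in particular. H1299, a human lung carcinoma line that makes no p53 protein, received 1 of 6 adenoviruses at a multiplicity of infection of 25, and total RNA was taken 24 h later. The viruses carried p53, p63a, p63g, p73a, p73b or, as the control, the bacterial beta-galactosidase gene LacZ. p63 and p73 are transcription factors related to p53, and the suffixes a, g and b name forms of each protein. The labels do not say which start of the p63 and p73 proteins was used. Each RNA was hybridised to 1 array with probes for protein-coding genes and for lincRNAs. Of 50599 probes, 46.6% were well above background on Ad-LacZ, 50.5% on Ad-p53, 49.8% on Ad-p63a, 45.9% on Ad-p63g, 47.5% on Ad-p73a and 48.4% on Ad-p73b. There was 1 array per group and no replicate, which limits the precision. No difference could be set against the spread between replicates, no p-value was computed, and every value below compares single arrays.

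TP63 and TP73 were read first. TP63, read by 1 probe (chromosome 3, 189586433 to 189586492, hg19), was at least 119-fold higher with Ad-p63a and at least 3120-fold higher with Ad-p63g than with Ad-LacZ. TP73 was 1638-fold higher with Ad-p73a and 4506-fold higher with Ad-p73b at its first probe (chromosome 1, 3649541 to 3649600), and 638-fold and 3007-fold higher at its other probe (chromosome 1, 3645911 to 3645970). The forms of 1 gene did not reach equal signals: TP63 signal was 26.2-fold higher with Ad-p63g than with Ad-p63a, and TP73 signal was 2.75-fold and 4.71-fold higher with Ad-p73b than with Ad-p73a at the 2 probes. These are ratios of probe signal from labelling that starts at the 3-prime end, not of protein.

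**Figure D1:**
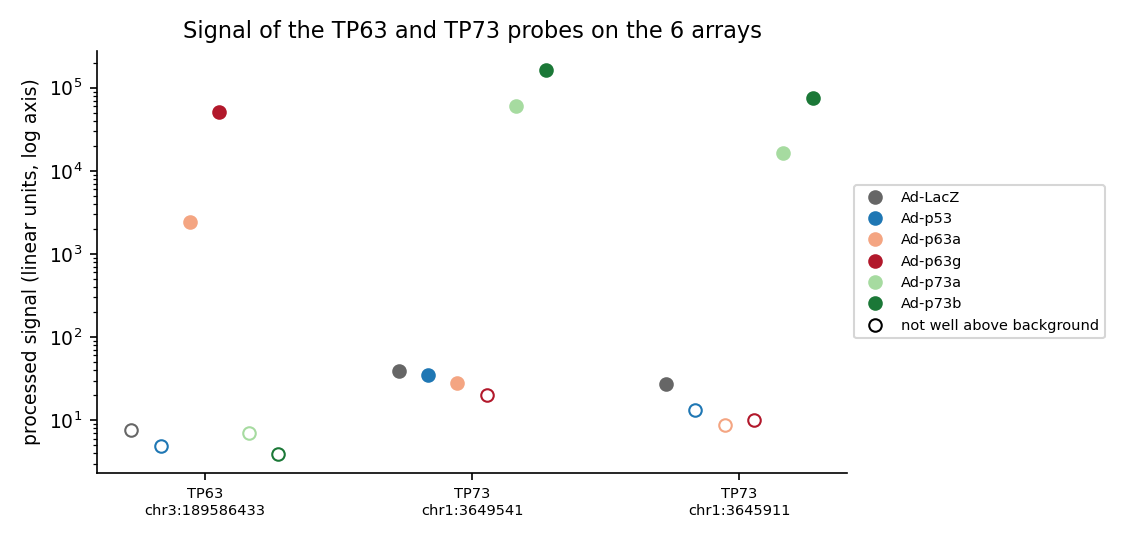
Processed signal (linear units on a log axis) of each TP63 and TP73 probe on the 6 arrays, with 1 point per array and open points where the probe was not well above background. Both genes have their highest signals on the arrays whose virus carried them, and TP63 signal is 26.2-fold higher with Ad-p63g than with Ad-p63a.

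Ad-p53 against Ad-LacZ addressed the response to p53 itself. Genes known as direct p53 targets were far higher with Ad-p53. BTG2, an antiproliferative gene, was 69.5-fold higher, MDM2, the ubiquitin ligase that degrades p53, 54.8-fold, the translesion polymerase POLH 42.2-fold and the cyclin-dependent kinase inhibitor CDKN1A 34.9-fold. Of 24 arrest, repair and feedback targets, 21 were at least 2-fold higher and 1 was lower (median log2 difference 2.76, percentile 100 among random lists). Of 21 apoptosis targets, 16 were higher and 2 lower (2.71, percentile 100). The apoptosome component APAF1 was at least 36.1-fold higher, TP53I3 30.98-fold and the death-domain adaptor PIDD1 19.3-fold, and IGFBP3, which binds insulin-like growth factors, at least 128-fold. Among metabolic targets, the glutaminase GLS2 was 101-fold and the pantothenate kinase PANK1 42.5-fold higher, with 6 of 12 members higher and 3 lower (1.17, percentile 99.8).

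Cell cycle genes were lower with Ad-p53. The mitotic kinase PLK1 was 15.9-fold lower, the centromeric histone CENPA 11.2-fold, cyclin A2 (CCNA2) 9.46-fold and the kinase AURKB 8.67-fold. Of 22 G2/M genes, 19 were at least 2-fold lower and 1 was higher (-2.18, percentile 0), and of 23 G1/S and replication genes 12 were lower and 2 higher (-1.04, percentile 0). In the latter list the ribonucleotide reductase subunit RRM2 was 6.24-fold lower while PCNA, the replication clamp and a known p53 target, was 6.17-fold higher. Replication-dependent histones had 5 of 9 measured members lower (-1.11, percentile 0.0700), among them H3C4 at 3.55-fold. Keratinocyte and epithelial adhesion genes stood on the other side, with 12 of 22 higher and 1 lower (1.93, percentile 100, and 1.10 with members at their bound). This list shares PERP with the list of p53 apoptosis targets, so the lists are not fully separate. SFN, which encodes 14-3-3 sigma, was 300.4-fold higher, the serpin SERPINB5 at least 30.1-fold and the laminin chain LAMA3 11.9-fold. In the Notch pathway, LFNG was at least 83.6-fold, the ligand JAG2 29.2-fold and the receptor NOTCH3 19.8-fold higher, with 5 of 13 members higher and 4 lower (0.87, percentile 99.5). Multiciliated cell genes (-0.20), housekeeping genes (-0.19) and ribosomal proteins (-0.03) had medians within the central 95% of random lists. FGFR3, a fibroblast growth factor receptor, was the highest at 341-fold among genes well above background on both arrays, and the mitotic kinase TTK (15.1-fold) and the Hedgehog effector GLI1 (13.9-fold) were among the lowest of these. Of 5 measured markers of endothelium and fibroblasts, 3 were higher (3.90, percentile 99.9, and 1.76 with members at their bound), namely smooth muscle actin ACTA2 at 50.3-fold, VWF at least 10.4-fold and PDGFRB at least 3.38-fold.

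In all, 2771 genes were at least 2-fold higher and 2605 at least 2-fold lower with Ad-p53, of 15451 considered. The count of 5376 became 3417 (2187 higher, 1230 lower) after normexp, and the split became 1777 to 5100 with spike-in scaling and 2117 to 3898 with median scaling. The Notch median lay within the central 95% in 6 of 15 alternatives, among them 0.25 with members at their bound, 0.20 in the authors' table and 0.032 with no detection filter, and with the mean over probes the endothelium and fibroblast median moved to 0.64, also within it.

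Ad-p63a gave the smallest difference from Ad-LacZ. SFN was 17.2-fold higher, and the ferredoxin reductase FDXR (7.21-fold), TP53INP1 (4.44-fold), PANK1 (4.29-fold), GLS2 (4.10-fold), MDM2 (3.92-fold) and BTG2 (3.75-fold) were among the others higher. The death receptor FAS was 2.83-fold, TP53I3 2.18-fold and the desmosome-associated gene PERP 2.03-fold higher. Of 24 arrest, repair and feedback targets 5 were higher and 0 lower (0.54, percentile 100), and of 18 apoptosis targets 3 were higher and 0 lower (0.47, percentile 100). No G2/M gene of 22 passed the size rule (percentile 34.9), and G1/S genes had 0 of 23 past it with a median of -0.25 (percentile 0.0300). The Notch ligand JAG2 was 2.75-fold higher and the Notch median was 0.38 (percentile 99.9). Medians of metabolic targets (0.25, and 0.083 with members at their bound), histones (-0.20), keratinocyte genes (0.05, with S100A2 2.22-fold higher), multiciliated cell genes (0.0056, and -0.046 at the bound), housekeeping genes (-0.0054) and ribosomal proteins (-0.08) lay within the central 95%. TMEM131L (10.1-fold) and C16orf90 (8.27-fold) were among the 5 highest genes well above background on both arrays, and UNC13D (15.6-fold) and AQP10 (12.1-fold) were the lowest of these, but the spots of all 4 lay in bright patches of 1 of the arrays.

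With Ad-p63a, 121 genes were higher and 188 lower of 14850 considered. Without spots in bright patches these were 118 and 126, and the keratinocyte median became 0.36 (percentile 99.9). The histone median lay outside the central 95% in 4 of 15 alternatives and that of metabolic targets in 1. The total of 309 became 127 (34 higher, 93 lower) after normexp and 172 (43 higher, 129 lower) in the authors' table, 60 to 477 with spike-in scaling and 95 to 245 with median scaling. More genes were higher than lower at the 1.5-fold threshold (815 and 673) and with no detection filter (746 and 583), and the Notch median fell within the central 95% after the probe GC trend was removed (0.21).

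Ad-p63g, like Ad-p53, gave a wide response. Among p53 targets, BTG2 was 32.5-fold, FDXR 21.7-fold, TP53INP1 15.4-fold and the sestrin SESN1 13.1-fold higher, with 18 of 24 arrest, repair and feedback members higher and 4 lower (2.26, percentile 100). Of 20 apoptosis targets 15 were higher and 2 lower (2.31, percentile 100), including IGFBP3 at least 173-fold and caspase-1 (CASP1) at least 16.6-fold. Metabolic targets went both ways (4 of 11 higher, 2 lower, 0.46, percentile 94.6). GLS2 was 47.8-fold higher, and SLC7A11, the cystine transporter that p53 is known to repress, was 19.5-fold lower, the lowest gene of those well above background on both arrays. G2/M genes were lower in 16 of 22 and higher in 2 (-1.40, percentile 0), led by CDC25C at 6.75-fold and PLK1 at 5.48-fold. G1/S genes had 8 of 23 lower and 2 higher (-0.62, percentile 2.94), with RRM2 12.2-fold lower and cyclin E1 (CCNE1) 4.16-fold higher, and histones had 3 of 9 lower and 1 higher (-0.70, percentile 2.98). Both medians lay within the central 95%, but outside it in 7 of 15 alternatives for G1/S genes and in 1 for histones.

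With Ad-p63g, SFN was 116-fold, S100A2 50.5-fold, LAMA3 10.1-fold and desmoplakin (DSP) 9.49-fold higher, and 9 of 18 measured keratinocyte and adhesion genes were higher with 1 lower (1.54, percentile 100). Notch pathway members were higher in 9 of 14 and lower in 2 (1.87, percentile 100, and 1.24 with members at their bound), with JAG2 at 24.9-fold, the Notch-regulated repressor NRARP at 13.9-fold and NOTCH3 at 8.32-fold. The transcription factor MYB (12.6-fold) and cyclin A1 (CCNA1, 17.1-fold) were higher in the multiciliated list, whose median of 0.30 lay within the central 95%, as did those of housekeeping genes (-0.07) and ribosomal proteins (-0.12). Among genes well above background on both arrays, BAMBI, a decoy receptor of the TGF-beta family, was the highest at 149-fold and the steroid dehydrogenase HSD11B2 was next at 128-fold. E2F2, an S-phase transcription factor (16.8-fold), and the tight junction protein CLDN1 (15.0-fold) were among the lowest of these. Of 7 lung epithelium markers 2 were higher, NKX2-1 by at least 47.4-fold and SFTPC by 6.03-fold (-0.14, percentile 50.8), and ACTA2 was 21.7-fold higher among 4 endothelium and fibroblast markers (0.43, percentile 68.0, and 0.060 with members at their bound). In all, 2849 genes were higher and 2883 lower of 14956. The total of 5732 was 3778 after normexp, and spike-in scaling split it 1885 to 5381. More genes were higher than lower in 7 of 17 alternatives, among them normexp, the authors' table and the 4-fold threshold.

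Ad-p73a gave a narrower response. SFN was 127-fold, FGFR3 76.6-fold, the forkhead gene FOXS1 26.8-fold and S100A2 21.7-fold higher. FDXR (7.70-fold), BTG2 (6.44-fold) and TP53INP1 (5.24-fold) led the arrest, repair and feedback targets, of which 7 of 24 were higher and 0 lower (0.45, percentile 100). Apoptosis targets were higher in 8 of 21 and lower in 0 (0.83, percentile 100), with IGFBP3 at least 6.50-fold and PIDD1 3.49-fold. PANK1 was 6.24-fold and GLS2 5.44-fold higher in the metabolic list (3 of 12 higher, 1 lower, 0.27, percentile 98.2). Notch ligands were higher, JAG2 by 15.3-fold and DLL1 by at least 4.60-fold, as were LFNG by at least 10.1-fold and NRARP by 4.42-fold (6 of 13 higher, 0 lower, 0.77, percentile 100). Among keratinocyte and adhesion genes 4 of 15 were higher (0.44, percentile 99.9), including the integrin ITGB4 at 3.59-fold and PERP at 3.35-fold.

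Cell cycle lists were shifted slightly with Ad-p73a. The medians were -0.18 for G2/M (0 of 22 past the size rule, percentile 1.20), -0.22 for G1/S (1 of 24 lower, percentile 0.320) and -0.23 for histones (0 of 9, percentile 1.45), and cyclin E2 (CCNE2) was 2.45-fold lower. Multiciliated cell genes (0.07), housekeeping genes (0.0023) and ribosomal proteins (-0.03) lay within the central 95%. In all, 739 genes were higher and 315 lower of 14683, and without bright patches 716 and 254. UNC13D (11.5-fold) and AQP10 (13.1-fold) were again among the lowest genes well above background on both arrays, from spots in bright patches. The total of 1054 was 560 after normexp and 663 in the authors' table, spike-in scaling split it 518 to 697, and the metabolic median moved within the central 95% with members at their bound (0.10) and with detection on all 6 arrays (0.25) and the histone median with quantile normalization (-0.22).

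Ad-p73b gave a wider response than Ad-p73a. FGFR3 was 408-fold, SFN 253-fold, RIMBP3 197-fold and SECTM1 187-fold higher. Of 24 arrest, repair and feedback targets 12 were higher and 1 lower (0.84, percentile 100), with PHLDA3, a repressor of AKT signalling, at least 15.8-fold, MDM2 11.7-fold and BTG2 11.4-fold. Of 21 apoptosis targets 11 were higher and 1 lower (1.06, percentile 100), including IGFBP3 at least 126-fold, CASP1 at least 17.6-fold and TP53AIP1 at least 16.8-fold. In the metabolic list 6 of 11 were higher and 2 lower (1.24, percentile 99.98), with GLS2 and PANK1 both 10.0-fold higher. G2/M genes were lower in 13 of 22 and higher in 0 (-1.09, percentile 0), led by CDC25C at 3.62-fold and BUB1 at 2.78-fold. The medians of G1/S genes (-0.53, percentile 0.0500) and histones (-0.96, percentile 0.0100) were below the central 95%, with 5 of 23 and 4 of 9 members past the size rule on the lower side, among them RRM2 at 3.16-fold and H4C8 at 2.88-fold.

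Keratinocyte and adhesion genes were higher in 15 of 24 and lower in 2 with Ad-p73b (1.73, percentile 100). S100A2 was 45.2-fold higher, the epidermal regulator ZNF750 at least 19.7-fold and basal keratin KRT14 at least 15.9-fold. JAG2 was 53.3-fold, LFNG at least 44.2-fold and DLL1 at least 39.1-fold higher in the Notch pathway (6 of 13 higher, 0 lower, 0.80, percentile 99.9). In the multiciliated list 5 of 12 were higher and 0 lower, among them CCNA1 (8.06-fold), MYB (4.66-fold) and TPPP3 (3.43-fold), and its median of 0.39 (percentile 95.8) lay within the central 95%, but outside it in 5 of 15 alternatives, up to 0.62 with detection on all 6 arrays. The medians of housekeeping genes (-0.22) and ribosomal proteins (-0.02) lay within it. The Wnt antagonist DKK1 (19.1-fold) and G0S2 (18.7-fold) were the lowest genes well above background on both arrays. Of the markers of other cell types, SFTPC was 31.1-fold, ACTA2 7.72-fold and VWF at least 4.18-fold higher. Lung epithelium markers as a list lay at 0.17 (percentile 83.2) and endothelium and fibroblast markers at 2.502 (percentile 99.3, 5 members). In all, 1684 genes were higher and 1357 lower of 15012. The total of 3041 was 1707 (1137 higher, 570 lower) after normexp and 5482 (954 higher, 4528 lower) with spike-in scaling, and the endothelium and fibroblast median moved within the central 95% with the mean over probes (0.27) and with members at their bound (0.35) and turned to -0.17 with no detection filter.

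**Figure D2:**
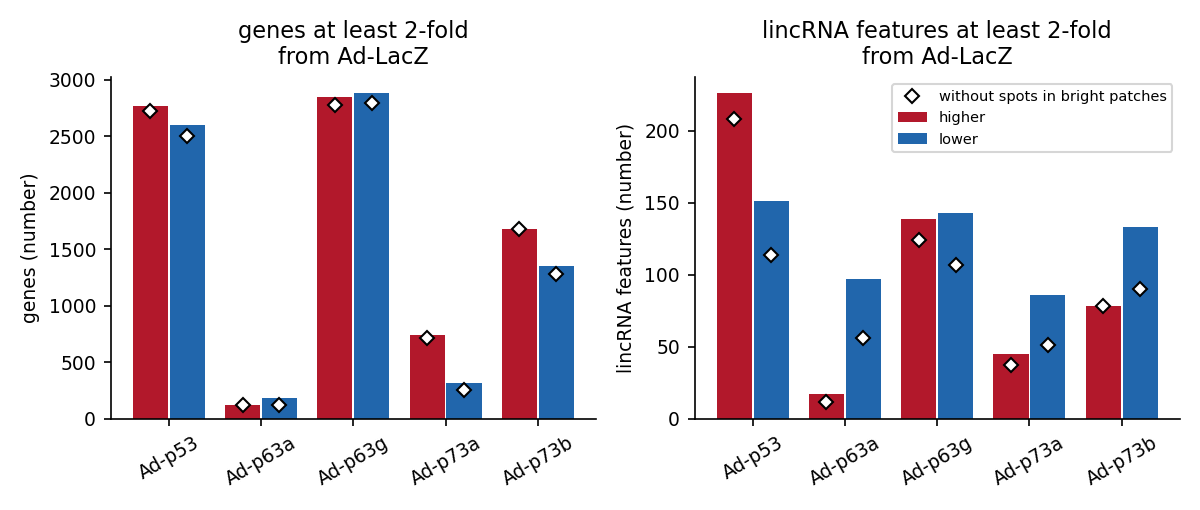
Number of genes (left) and lincRNA features (right) at least 2-fold higher (red) or lower (blue) than Ad-LacZ in each infection, from 1 array each, with diamonds for the counts without spots in bright patches. Ad-p53 and Ad-p63g have the most genes past the size rule, 5376 and 5732, and Ad-p63a the fewest, 309.

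**Figure D3:**
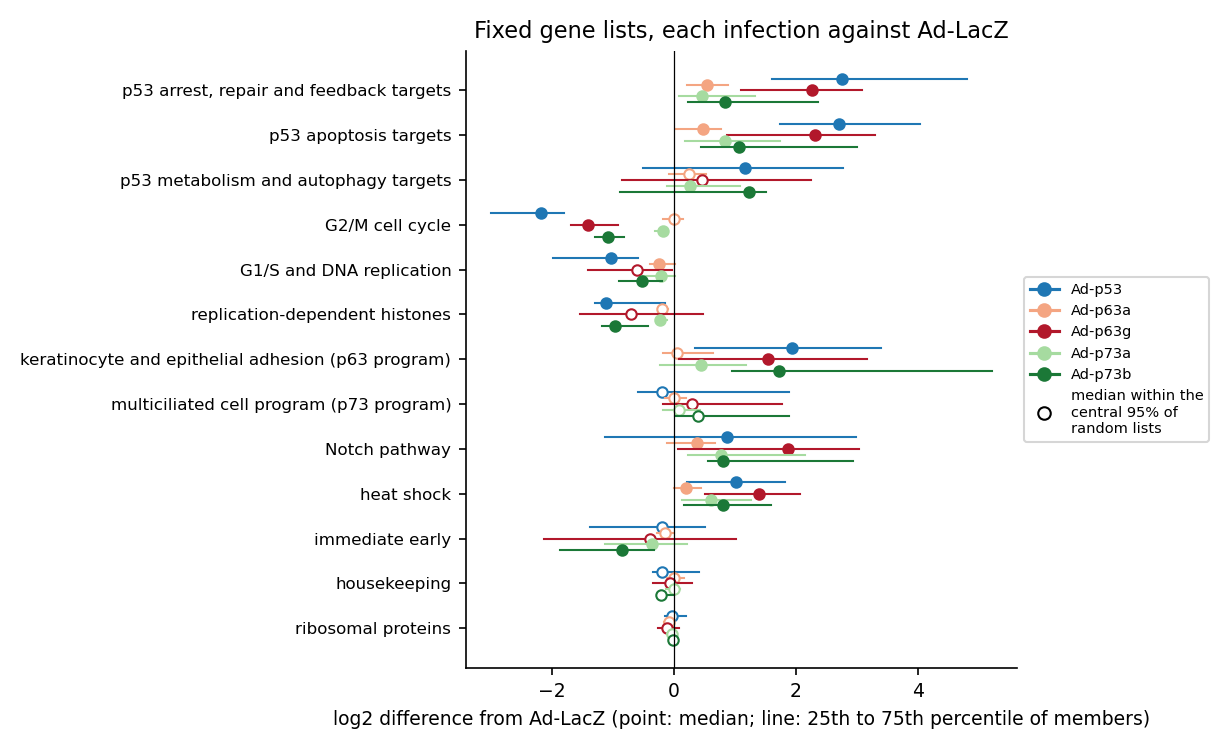
Median log2 difference from Ad-LacZ of 13 gene lists in each infection (points) with the 25th to 75th percentile of the members (lines), open points being medians within the central 95% of matched random lists. The p53 arrest and apoptosis target lists lie above 0 in all 5 infections, and the G2/M list lies lowest with Ad-p53 (-2.18), Ad-p63g (-1.40) and Ad-p73b (-1.09).

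The forms of p63 were compared with each other directly, without Ad-LacZ. With Ad-p63g, CDKN1A was 8.83-fold, BTG2 8.67-fold, POLH 8.42-fold and SESN1 6.30-fold higher than with Ad-p63a, and 16 of 24 arrest, repair and feedback targets were higher and 3 lower (1.52, percentile 100). Of 20 apoptosis targets 14 were higher and 3 lower (1.60, percentile 100), with IGFBP3 at least 233-fold and CASP1 at least 22.4-fold. G2/M genes were lower in 14 of 22 and higher in 2 (-1.46, percentile 0), with CDC25C 6.65-fold and the topoisomerase TOP2A 4.86-fold lower. S100A2 (22.8-fold), LAMA3 (9.46-fold), NRARP (10.72-fold) and JAG2 (9.06-fold) were higher, in a keratinocyte list with 9 of 18 higher and 1 lower (1.52, percentile 100) and a Notch list with 7 of 14 higher and 2 lower (1.13, percentile 99.9). The Hedgehog ligand IHH was the highest at 282-fold and SLC7A11 the lowest at 24.8-fold lower among genes well above background on both arrays. The homeobox gene NKX2-1 was 54.0-fold higher in the lung epithelium list (0.46, percentile 88.5).

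Medians between the p63 forms lay within the central 95% for metabolic targets (0.41), G1/S genes (-0.26), histones (-0.45), multiciliated cell genes (0.02, and 0.12 with members at their bound), housekeeping genes (-0.0020), ribosomal proteins (-0.04) and endothelium and fibroblast markers (-0.29), although the metabolic median lay outside it in 3 of 15 alternatives (0.96 with detection on both arrays). In all, 2751 genes were higher and 2964 lower with Ad-p63g of 15236, and 167 and 112 lincRNA features of 1407. The total of 5715 genes was 3622 after normexp. More genes were higher than lower in 6 of 16 alternatives, among them normexp, median scaling and the 4-fold threshold. Spike-in scaling split the lincRNA features 135 to 141. The lincRNA total of 279 was 94 after normexp, 125 in the authors' table, 164 with detection on both arrays and 132 on all 6 arrays, where 59 were higher and 73 lower.

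Between the forms of p73, fewer p53 targets passed the size rule than between the forms of p63, a difference that was not tested. MDM2 (4.75-fold), PHLDA3 (4.04-fold), CDKN1A (4.03-fold) and AEN (3.95-fold) were the 4 arrest, repair and feedback targets of 24 that were higher with Ad-p73b (0.26, percentile 99.9). IGFBP3 (19.4-fold) and TP53AIP1 (16.7-fold) led the apoptosis targets, of which 6 of 21 were higher and 1 lower (0.25, percentile 99.7). Keratinocyte and adhesion genes were higher in 11 of 24 and lower in 0 (1.02, percentile 100), with ZNF750 at least 19.4-fold, KRT14 at least 17.9-fold and the water channel AQP3 at least 12.2-fold. Multiciliated cell genes were higher in 4 of 12 (0.49, percentile 99.3), with MYB at 4.63-fold and TPPP3 at 3.82-fold. G2/M genes had 4 of 22 lower and 0 higher (-0.83, percentile 0), led by CDC25C at 3.22-fold, and histones 2 of 9 lower (-0.64, percentile 0.0200). The troponin TNNI2 was the highest at 65.4-fold among genes well above background on both arrays. B4GALT4, the lowest of these at 24.1-fold lower, was read by a spot in a bright patch.

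Metabolic targets (0.15), G1/S genes (-0.24), the Notch list (0.13), housekeeping genes (-0.12) and ribosomal proteins (0.05) lay within the central 95% between the p73 forms, although DLL1 was 8.50-fold and LFNG 4.35-fold higher with Ad-p73b and the G1/S median lay outside it in 3 of 15 alternatives. Endothelium and fibroblast markers lay at 1.10 (percentile 96.6, and 0.52 with members at their bound) and lung epithelium markers at 0.48 (percentile 98.5), with SFTPC 14.5-fold higher, and the lung epithelium median moved within the central 95% with the mean over probes (0.35) and after the probe GC trend was removed (0.26). In all, 931 genes were higher and 427 lower of 14918, and 45 and 42 lincRNA features of 1276. The gene total of 1358 was 649 after normexp and 775 (616 higher, 159 lower) in the authors' table, median scaling split it 811 to 579 and spike-in scaling 580 to 1406. Spike-in scaling also turned the arrest and apoptosis medians to -0.06 and -0.07, still at percentiles 99.9 and 99.7, and split the lincRNA features 22 to 107, against 36 to 51 with median scaling. The lincRNA total of 87 was 17 after normexp, 29 in the authors' table, 49 with detection on both arrays and 26 on all 6 arrays.

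LincRNA expression was the stated purpose of the experiment. Ad-p53 had 226 lincRNA features at least 2-fold higher and 151 lower of 1520 considered, Ad-p63a 17 and 97 of 1399, Ad-p63g 139 and 143 of 1293, Ad-p73a 45 and 86 of 1292, and Ad-p73b 78 and 133 of 1324. XLOC_l2_010854 (chromosome 4, 138972483 to 138983985) was higher in all 5 infections, from 5.22-fold with Ad-p63a to 7.70-fold with Ad-p53. XLOC_010881 (chromosome 14, 77432137 to 77432196) was likewise higher in all 5, by at least 2.98-fold with Ad-p63a and at least 181-fold with Ad-p73b, and XLOC_l2_004706 (chromosome 15, 69355019 to 69355078) by 2.39-fold to 3.20-fold. These belonged to 6 lincRNA features higher in all 5 infections. LincRNA features at least 2-fold below all other arrays numbered 4 on Ad-p53, 5 on Ad-p63a and 12 on Ad-p63g. They numbered 0 on Ad-p73a and 2 on Ad-p73b. A low signal on the Ad-LacZ array could not be told apart from a rise in all 5 infections. Among features well above background on both arrays, XLOC_l2_007783, for which the files give no coordinates, was the highest with Ad-p63g (74.8-fold), Ad-p73a (7.598-fold) and Ad-p73b (19.4-fold). XLOC_l2_005714 (chromosome 17, 21905090 to 21905149) was 24.7-fold higher with Ad-p53 and 9.18-fold higher with Ad-p73b. XLOC_014174 (chromosome 22, 23893653 to 23893712) was lower with Ad-p63g (8.40-fold), Ad-p73a (9.99-fold) and Ad-p73b (8.63-fold), and was 1 of the 49 lincRNA features lower in all 5 infections. Its mean log2 difference over the 5 was -3.01, and its spot lay outside the bright patches of Ad-LacZ. A high signal of that spot could not be told apart from a fall in all 5 infections. XLOC_013370 (chromosome 19, 47742558 to 47742617) was 20.2-fold lower with Ad-p63g. XLOC_011535 (85.1-fold higher with Ad-p53) and XLOC_013838 (14.3-fold lower with Ad-p53 and 18.3-fold lower with Ad-p73b) were read by spots in bright patches.

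Among 30 long noncoding RNAs known by name, H19, an imprinted fetal transcript, was at least 203-fold higher with Ad-p53, at least 2.53-fold with Ad-p73a and at least 11.98-fold with Ad-p73b. TP53TG1, a known p53-induced transcript, was 8.08-fold higher with Ad-p53. The snoRNA host gene SNHG1 was 5.64-fold lower with Ad-p53 and 10.1-fold lower with Ad-p63g, and EPB41L4A-AS1 was 5.997-fold and SNHG12 4.85-fold lower with Ad-p63g. CDKN2B-AS1 was at least 4.71-fold lower with Ad-p53 and 3.93-fold lower with Ad-p73b, and NEAT1, the scaffold of paraspeckles, was 3.33-fold lower with Ad-p73b at the probe that stands for it. The list had 4 of 25 members higher and 6 lower with Ad-p53 (-0.20, percentile 22.8), 0 and 0 of 25 with Ad-p63a (0.04, percentile 53.2, and -0.025 with members at their bound), 2 and 11 of 23 with Ad-p63g (-0.76, percentile 0.230), 1 and 0 of 24 with Ad-p73a (-0.20, percentile 0.420), and 2 and 4 of 24 with Ad-p73b (-0.37, percentile 0.690). Between forms it lay at -0.50 for p63 (percentile 4.33) and -0.19 for p73 (percentile 8.85), outside the central 95% in 4 and 2 of 15 alternatives. It moved within the central 95% with no detection filter for Ad-p63g (-0.52) and Ad-p73b (-0.30) and with the mean over probes for Ad-p73a (-0.13).

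Probes along NEAT1 were examined after their values were seen. The distal probe (chromosome 11, 65206777 to 65206836) was 2.48-fold higher with Ad-p53, while the 4 proximal probes, between 65192168 and 65193944, lay between -1.32 and -0.20. The distal probe lay above the mean of the proximal ones by 2.06 on log2 scale with Ad-p53, 1.60 with Ad-p63g and 1.54 with Ad-p73b, by 0.34 with Ad-p73a and by -0.41 with Ad-p63a, where the proximal probes lay between 0.86 and 1.06.

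**Figure D4:**
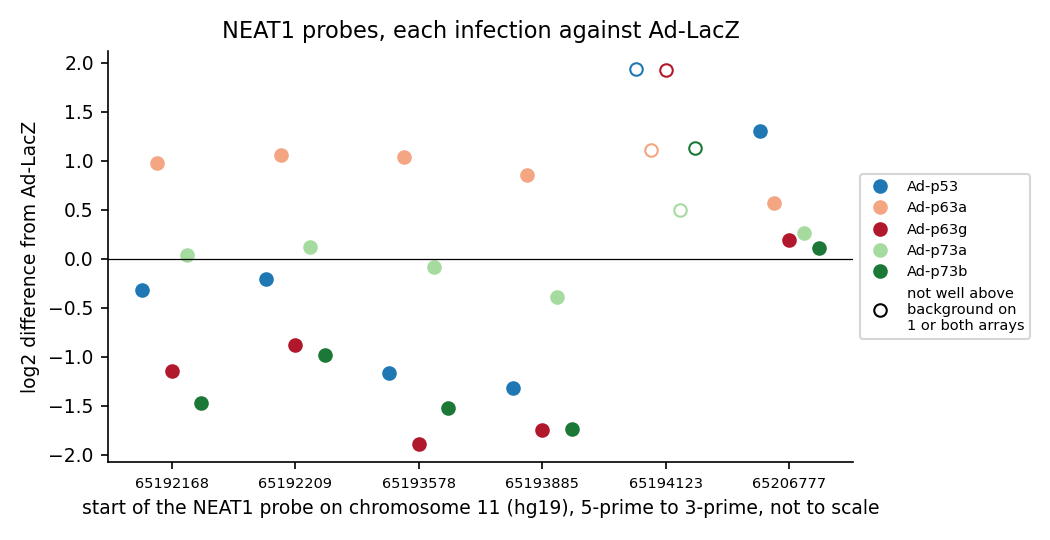
Log2 difference from Ad-LacZ at each NEAT1 probe, in order along chromosome 11 (hg19, not to scale), with 1 point per infection and open points where the probe was not well above background on 1 or both arrays. The last probe lies at 1.31 with Ad-p53, above the 4 proximal probes, which lie between -1.32 and -0.20.

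LincRNA counts depended on dim probes and on local brightness. Without spots in bright patches, Ad-p63a had 12 higher and 56 lower lincRNA features, Ad-p73a 37 and 51, Ad-p73b 78 and 90, Ad-p63g 124 and 107, and Ad-p53 208 and 114. With detection required on both arrays the totals were 173 for Ad-p53, 34 for Ad-p63a, 135 for Ad-p63g, 44 for Ad-p73a and 86 for Ad-p73b. The lower side no longer held more lincRNA features for Ad-p73a without features lit on Ad-LacZ alone (45 higher, 39 lower) and with detection on all 6 arrays (18 and 17), and with detection on both arrays the split was 21 to 23. For Ad-p73b these splits were 78 to 80, 36 to 35 and 39 to 47, and with no detection filter Ad-p63a had 409 and 401. For Ad-p53 the split was 195 higher to 216 lower with quantile normalization, 166 to 239 with median scaling, 143 to 329 with spike-in scaling and 145 to 35 after normexp. Spike-in scaling gave 8 higher to 163 lower for Ad-p63a, 82 to 310 for Ad-p63g, 26 to 124 for Ad-p73a and 32 to 333 for Ad-p73b.

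A total of 68 genes were at least 2-fold higher in all 5 infections. SFN (from 17.2-fold to 300.4-fold), FDXR (from 6.74-fold to 28.9-fold), PANK1, GLS2, BTG2, ACTA2 and RIMBP3 were among the 10 whose smallest difference was largest. The adhesion gene NECTIN4 was higher by at least 3.44-fold with Ad-p63a and at least 24.0-fold with Ad-p73b. A total of 75 genes and 49 lincRNA features were lower in all 5. Of these 124 features, 65 were read on the Ad-LacZ array by spots in bright patches, and without such spots 35 genes and 23 lincRNA features were lower in all 5, against 67 genes and 6 lincRNA features higher in all 5. The number of genes higher in all 5 was 23 after normexp, 27 in the authors' table and 36 with spike-in scaling, and of lincRNA features 1, 1 and 3. With detection required on both arrays, 13 genes and 5 lincRNA features were lower in all 5 and 53 and 2 were higher.

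**Figure D5:**
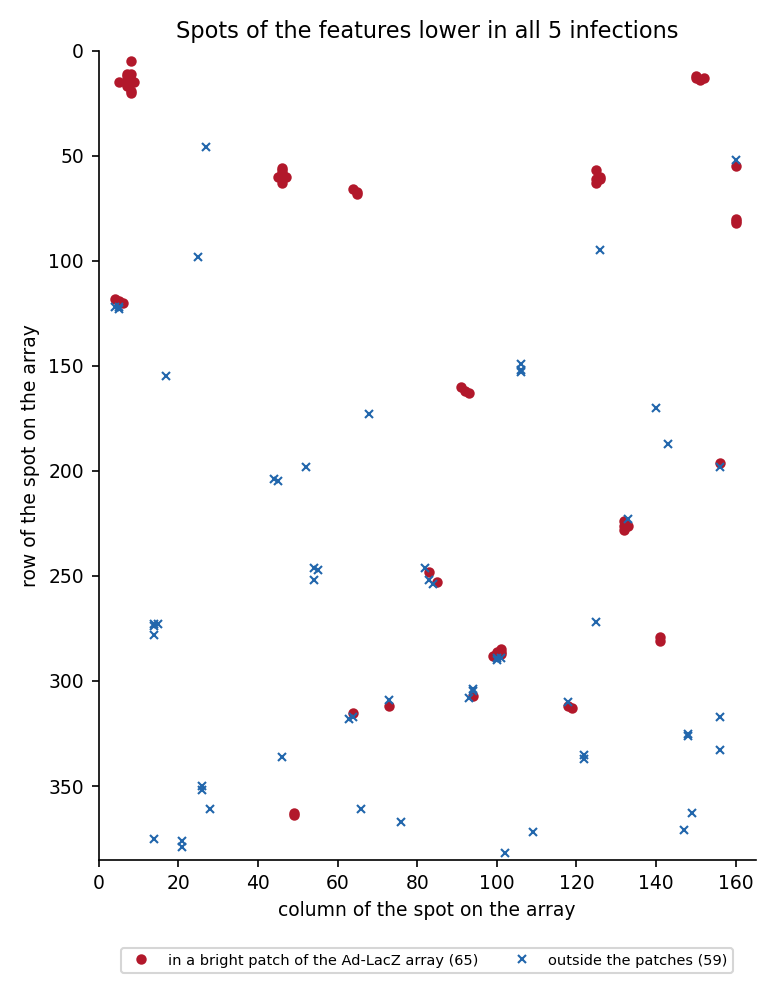
Row and column on the Ad-LacZ array (number of spots) of the spots behind the 124 features lower in all 5 infections, with red circles inside bright patches and blue crosses outside. The spots lie in clusters, with 65 inside the patches and 59 outside.

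Ad-p53, Ad-p63g and Ad-p73b shared 864 higher and 647 lower genes, where independent lists of these sizes would share 47.3 and 48.2 of 14534 genes. They shared 25 higher and 77 lower lincRNA features, against 0.532 and 2.09 of 1171 for independent lists. Of the 77, 49 were lower in all 5 infections, 39 were well above background on the Ad-LacZ array alone, and 27 were read there by a spot in a bright patch, which left 31 with neither. Of the 647 lower genes these were 75, 49 and 49, which left 578. Ad-p53 and Ad-p63g shared 1580 higher and 1605 lower genes (464 and 511 for independent lists), and 124 genes were past the size rule in opposite directions. Of the 723 genes higher with Ad-p73a and considered for both p73 forms, 647 (89.5%) were also higher with Ad-p73b, against 76.1 for independent lists. Of the 109 genes higher with Ad-p63a and considered for both p63 forms, 88 (80.7%) were also higher with Ad-p63g, against 19.1 for independent lists. Of the 188 lower genes, 92 (48.9%) were also lower, against 37.6. Unchanged arrays set against 1 shared control gave 143 shared higher and 146 shared lower genes at the upper noise, and 0 at the noise of replicate spots. Unlike the counts above, these simulated counts used neither a detection filter nor bounds, so they are only a rough guide. With 1 control array the control could not be split, so part of each excess may come from that array. For the p63 forms, the 88 and 92 shared genes lay below the simulated counts at the upper noise. That noise called 7.81% of unchanged genes, while 2.08% of genes were called for Ad-p63a. The simulated and real counts are thus not comparable there, and how much of the excess comes from that array stays open.

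Across 16185 genes, which are not independent replicates, the differences from Ad-LacZ correlated most between Ad-p73a and Ad-p73b (Pearson's r 0.76). The r was 0.69 for Ad-p63g and Ad-p73b, 0.68 for Ad-p53 and Ad-p63g, 0.65 for Ad-p53 and Ad-p73b, 0.63 for Ad-p63g and Ad-p73a, 0.57 for Ad-p53 and Ad-p73a and 0.54 for Ad-p63a and Ad-p73a. It was 0.36 for Ad-p63a and Ad-p53, 0.34 for Ad-p63a and Ad-p63g and 0.29 for Ad-p63a and Ad-p73b. Unchanged arrays sharing the control gave an r of 0.50 on average and 0.52 at most. Equal noise was given to the infections and the control, which fixes this r near 0.50 at either noise level. Real arrays differ in spread, so an r above or below it does not measure the share of the control. The covariance was 1.57 for Ad-p53 and Ad-p63g, 1.24 for Ad-p63g and Ad-p73b, 0.69 for Ad-p73a and Ad-p73b, 0.31 for Ad-p53 and Ad-p63a, 0.30 for Ad-p63a and Ad-p63g, 0.24 for Ad-p63a and Ad-p73a and 0.20 for Ad-p63a and Ad-p73b, beside 0.16 from the shared control at the upper noise. The r of Ad-p63a and Ad-p73a lay between 0.44 and 0.63 over the alternatives, on either side of the simulated values.

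Different probes of 1 gene gave an internal check. Of 1446 genes with 2 or more measured probes and any probe past the size rule for Ad-p53, 602 (41.6%) had all probes past it in 1 direction, and 11 had probes past it in opposite directions. The share was 46.0% of 1542 genes for Ad-p63g, 37.8% of 801 for Ad-p73b, 22.6% of 252 for Ad-p73a and 5.10% of 98 for Ad-p63a. The difference from Ad-LacZ was related to probe GC content across genes for Ad-p63a (Pearson's r -0.37) more than for Ad-p73b (0.15), Ad-p53 (-0.04), Ad-p63g (-0.03) or Ad-p73a (-0.03). Between forms, the r with probe GC content was 0.24 for Ad-p73b minus Ad-p73a and 0.08 for Ad-p63g minus Ad-p63a.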

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

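Chosen only after the result was seen were the tests of scaling and background for the 2 form comparisons, the test of background correction and normalization for NEAT1, the test of the long NEAT1 isoform, the values outside bright patches, the need for more than 3 genes with a further probe, and the need for enough genes with agreeing probes.

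The 124 features (75 genes and 49 lincRNA features) at least 2-fold lower than Ad-LacZ in all 5 infections could be RNAs lowered by every p53 family member or a fault of the shared Ad-LacZ array. Of these, 103 had another one within 5 rows and 5 columns on the array, against a median of 25 and a central range of 14 to 38 for random draws, which is consistent with local spot artefacts, and of the 59 outside the bright patches 33 still had such a neighbour (random median 6, upper limit 13). That every array holds as many such features is argued against by Ad-p63a and Ad-p73a, where 16 and 25 features were at least 2-fold above all other arrays against 124 on Ad-LacZ, while the 911 on Ad-p53, 816 on Ad-p63g and 223 on Ad-p73b may hold responses to those viruses. Features well above background on 1 array alone, whatever their difference, were more frequent on Ad-p63a (215 genes and 94 lincRNA features) than on Ad-LacZ (103 and 82), and the other probes of the same genes (median -0.39) decided nothing because only 3 genes had one. A response shared by all 5 infections was not tested apart from this and stays open for single features.

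Ad-p63g gave more genes past the size rule than Ad-p63a, and Ad-p73b more than Ad-p73a. Scaling and background correction were excluded as the whole cause, since the lowest ratio of the counts was 13.5 for p63 (18.6 in the main setting) and 2.86 for p73 (2.89 in the main setting). Less transgene RNA with Ad-p63a predicts that most genes past the size rule lie further out with Ad-p63g, and 44.3% of 244 did, with 69.2% of the 120 higher and 20.2% of the 124 lower ones. This decides nothing and leaves it open, since genes chosen as far out on the Ad-p63a array lie less far out on another by that choice alone, and of 98 genes with several measured probes and any past the size rule only 5 had all of them past it. For p73, 75.03% of 997 genes lay further out with Ad-p73b (77.4% of 942 outside bright patches) in spite of the same choice, at the edge of the share required. It was 78.9% of the 738 higher but only 64.1% of the 259 lower genes, short of it. Less transgene RNA with Ad-p73a thus stays possible for the higher ones and is undecided for the lower ones. A stronger effect of the p73b form itself predicts the same, so the share cannot tell them apart. The forms themselves, which the design names, stay open as untested.

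The distal NEAT1 probe lay 2.06 above the proximal ones with Ad-p53. A shift of labelling towards the 3-prime end common to most genes was argued against, since the median difference between the outermost probes of 3508 genes was 0.0657. The distance between those probes was not matched to that along NEAT1, so an effect of labelling over such a distance was not tested. Background correction and quantile normalization were excluded as the whole cause, with gaps of 1.72 after normexp, 2.11 with quantile normalization and 2.02 in the authors' value table, and scaling by 1 constant per array cancels from the gap and was not tested. A candidate explanation is a larger share of the long NEAT1 isoform, but the only other probe beyond the proximal ones gave a bound of 0.18, short of the 2-fold it needed and above 0, which decides nothing. It remains a hypothesis from 1 distal probe on 1 array.

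Some results went opposite ways between infections, and these differences were not tested. The cholesterol synthesis median was 0.22 with Ad-p63a (-0.096 with spike-in scaling) and -0.59 with Ad-p53, 0.81 apart, but it moved within the central 95% of random lists in 5 and 3 of 15 alternatives. RFX2, a transcription factor of ciliated cells, lay at 1.36 with Ad-p73b and -1.36 with Ad-p53, 2.72 apart. Probes with neither a gene nor a lincRNA name, which entered none of the counts above, also differed from Ad-LacZ. Of 10308 such probes, 3902 were considered for Ad-p53, 3695 for Ad-p63a, 3534 for Ad-p63g, 3499 for Ad-p73a and 3611 for Ad-p73b. Of those considered, 558 were at least 2-fold higher with Ad-p53, 47 with Ad-p63a, 443 with Ad-p63g, 107 with Ad-p73a and 214 with Ad-p73b, and 427, 125, 477, 128 and 315 were lower.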

How the results depend on the processing

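Chosen only after seeing the data were the alternatives of the 75th percentile over all probes, spike-in scaling, removal of the probe GC trend, leaving out features lit on Ad-LacZ alone, all probes of a gene past the threshold, and leaving out bright patches. No paired analysis was possible because each group has 1 array, and for the same reason neither leaving out a replicate nor a slide block could be run. Of 2283 list medians under an alternative, 2186 kept their side of the central 95%, 47 newly left it and 41 newly fell within it. The other 9 changed sign and lay outside it in the main or the alternative setting. Changes of sign with both medians within it were not counted and are among the 2186. Of 120 correlations 115 kept their side of the simulated value and 5 did not. That value follows from the equal noise of the simulated arrays. Median scaling, the 75th percentile over all probes and spike-in scaling shift each array by 1 constant. They could therefore move no percentile and no correlation. These settings hold 153, 153 and 148 of the kept medians and 10 correlations each, which check nothing. They are also among the alternatives counted for list medians in the text. All 32 values of TP63 and TP73 kept their sign and stayed at least 1 in size on log2 scale. The main differences lay between 8.25 and 12.96, so this check could hardly fail and does not show that the folds stayed equal. Of 598 counts, 377 moved by at most 1.5 times and 221 by over 1.5 times. Signal over background limits the lincRNA counts, since 16.2% of lincRNA features were well above background on Ad-LacZ. The cause was not tested where none is named.

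Of the counts that moved over 1.5 times, 92 were of single comparisons, 28 of features in all 5 infections and 101 of genes shared by 2 infections, and the last are not listed singly. Values are given in the order Ad-p53, Ad-p63a, Ad-p63g, Ad-p73a and Ad-p73b against Ad-LacZ. With normexp background correction they were 3417, 127, 3778, 560 and 1707 genes, 3622 genes between the p63 forms, 649 between the p73 forms, and 180, 47, 115, 46 and 68 lincRNA features. By construction the 1.5-fold threshold gave more, 8560, 1488, 8924, 2711 and 6026 genes, 9004 and 3899 between forms, and 675, 284, 534, 299 and 447 lincRNA features. The 4-fold threshold gave fewer, 1655, 77, 1724, 260 and 821 genes, 1583 and 278 between forms, and 139, 46, 101, 43 and 67 lincRNA features. All probes of a gene past the threshold, which only genes with several probes can meet, left 602, 5, 710, 57 and 303 genes. In the authors' value table there were 172 genes for Ad-p63a, 663 for Ad-p73a and 775 between the p73 forms, and 208, 57, 156, 63 and 95 lincRNA features. Detection on both arrays, which removes features, gave 186 genes for Ad-p63a and 173, 34, 135, 44 and 86 lincRNA features. Detection on all 6 arrays gave 162 genes for Ad-p63a, 866 between the p73 forms, and 153, 30, 129, 35 and 71 lincRNA features. With no detection filter there were 1329 genes for Ad-p63a, 2100 for Ad-p73a, 2462 between the p73 forms, and 1152, 810, 1007, 736 and 863 lincRNA features. Spike-in scaling gave 537 genes for Ad-p63a, and 5482 genes and 365 lincRNA features for Ad-p73b. Leaving out bright patches left 68 lincRNA features for Ad-p63a, and leaving out features lit on Ad-LacZ alone left 57 for Ad-p63a and 84 for Ad-p73a. The wider lincRNA class gave 446 for Ad-p63g.

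LincRNA features between the p63 forms numbered 94 after normexp, 125 in the authors' value table, 164 with detection on both arrays, 132 on all 6, 1120 with no detection filter, 547 and 73 at 1.5-fold and 4-fold, and 445 in the wider class. Between the p73 forms they numbered 17, 29, 49, 26, 743, 276 and 15 in that order up to 4-fold. In the order genes higher, genes lower, lincRNA features higher and lincRNA features lower in all 5 infections, there were 23, 34, 1 and 20 after normexp, 175, 163, 27 and 131 with no detection filter, 5, 38, 1 and 31 at 4-fold, and 36, 131, 3 and 78 with spike-in scaling. Higher in all 5 were 27 genes and 1 lincRNA feature in the authors' value table. With detection on both or on all 6 arrays 13 genes and 5 lincRNA features were lower and 2 lincRNA features higher. Genes and lincRNA features lower in all 5 were 35 and 23 without bright patches and 26 and 10 without features lit on Ad-LacZ alone. The side with more genes turned in 8, 3, 7, 1 and 2 of 17 alternatives for the 5 infections and in 6 and 2 of 16 between the p63 and p73 forms, and that with more lincRNA features in 3, 1, 5, 2 and 1, and in 2 and 3, of 17.

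List medians that newly fell within the central 95% follow by setting. In the authors' value table these were Notch (0.20) and cholesterol synthesis (-0.53) for Ad-p53, and heat shock (0.17), cholesterol synthesis (0.15) and endothelium and fibroblast (0.24) for Ad-p63a. With detection on both arrays they were Notch for Ad-p53 (0.56) and NF-kB for Ad-p63g (-0.78), and on all 6 arrays Notch for Ad-p53 (0.56), cholesterol synthesis for Ad-p63a (0.12) and p53 metabolism targets for Ad-p73a (0.25). With no detection filter they were Notch (0.032) and NF-kB (-0.22) for Ad-p53, heat shock (0.19), cholesterol synthesis (0.12) and endothelium and fibroblast (0.020) for Ad-p63a, long noncoding RNAs for Ad-p63g (-0.52) and Ad-p73b (-0.30), and immediate early genes for Ad-p73a (-0.079). With the mean over probes they were Notch (0.065), cholesterol synthesis (-0.53) and endothelium and fibroblast (0.64) for Ad-p53, endothelium and fibroblast for Ad-p63a (0.039) and Ad-p73b (0.27), long noncoding RNAs for Ad-p73a (-0.13) and lung epithelium between the p73 forms (0.35). With members at their bound they were Notch for Ad-p53 (0.25), endothelium and fibroblast for Ad-p63a (0.19) and Ad-p73b (0.35), and p53 metabolism targets (0.10) and EMT (-0.17) for Ad-p73a. After normexp they were NF-kB for Ad-p53 (-0.23), cholesterol synthesis (0.083) and endothelium and fibroblast (0.12) for Ad-p63a and EMT for Ad-p73a (-0.13). Without bright patches they were cholesterol synthesis for Ad-p53 (-0.58) and the unfolded protein response between the p63 forms (-0.44). With the probe GC trend removed they were Notch (0.21), heat shock (0.17) and cholesterol synthesis (0.094) for Ad-p63a and lung epithelium between the p73 forms (0.26), and with quantile normalization histones for Ad-p73a (-0.22). The correlation of Ad-p63a and Ad-p73a moved below the simulated maximum in the authors' value table (0.50), with detection on all 6 arrays (0.47), after normexp (0.48), without bright patches (0.49) and without features lit on Ad-LacZ alone (0.44).

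Other list medians newly left the central 95%. In the authors' value table these were the unfolded protein response for Ad-p53 (-0.64) and Ad-p73a (-0.21), immediate early genes for Ad-p63a (-0.19), G1/S for Ad-p63g (-0.71), multiciliated genes for Ad-p73b (0.37), NF-kB (-0.70) and long noncoding RNAs (-0.55) between the p63 forms, and G1/S (-0.24) and long noncoding RNAs (-0.23) between the p73 forms. With the mean over probes they were p53 metabolism targets (0.25) and immediate early genes (-0.18) for Ad-p63a, G1/S for Ad-p63g (-0.74), and G1/S and long noncoding RNAs between the p73 forms (both -0.24). With detection on both arrays they were histones for Ad-p63a (-0.20), G1/S for Ad-p63g (-0.62), NF-kB (0.26) and the unfolded protein response (-0.20) for Ad-p73a, multiciliated genes for Ad-p73b (0.39), and p53 metabolism targets (0.96) and long noncoding RNAs (-0.72) between the p63 forms. On all 6 arrays they were G1/S (-0.64) and histones (-0.70) for Ad-p63g, the unfolded protein response for Ad-p73a (-0.20), multiciliated genes for Ad-p73b (0.62), and p53 metabolism targets (0.96) and long noncoding RNAs (-0.72) between the p63 forms. With no detection filter they were histones for Ad-p63a (-0.20) and G1/S for Ad-p63g (-0.64). Without bright patches they were histones (-0.20) and keratinocyte genes (0.36) for Ad-p63a, and without features lit on Ad-LacZ alone histones for Ad-p63a (-0.20). With the probe GC trend removed they were immediate early genes for Ad-p63a (-0.15), multiciliated genes (0.53) and NF-kB (-0.59) for Ad-p73b, NF-kB between the p63 forms (-1.02) and G1/S between the p73 forms (-0.26). After normexp they were G1/S for Ad-p63g (-0.61), multiciliated genes for Ad-p73b (0.37), and NF-kB (-0.55) and long noncoding RNAs (-0.47) between the p63 forms. With quantile normalization they were G1/S for Ad-p63g (-0.68), the unfolded protein response for Ad-p73a (-0.22) and endothelium and fibroblast between the p73 forms (1.12). With members at their bound they were NF-kB for Ad-p73a (0.24), and p53 metabolism targets (0.62) and NF-kB (-0.80) between the p63 forms.

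The 9 medians that changed sign were, with spike-in scaling, heat shock (-0.13) and cholesterol synthesis (-0.10) for Ad-p63a and p53 arrest targets (-0.060), p53 apoptosis targets (-0.065) and heat shock (-0.055) between the p73 forms. By construction that scaling moves every gene of a comparison by 1 constant. The others were EMT for Ad-p63a with detection on all 6 arrays (-0.34), NF-kB for Ad-p63g (0.084) and endothelium and fibroblast for Ad-p73b (-0.17) with no detection filter, and NF-kB for Ad-p73a with the mean over probes (-0.48).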

Other observations

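No test was run for the values in this part, and none of its gene lists was chosen after the result was seen.

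Among heat shock genes, HSPA1B, an inducible HSP70 chaperone, was 17.1-fold higher with Ad-p53 and 21.02-fold higher with Ad-p63g, and the co-chaperone BAG3 3.59-fold higher with Ad-p73a and 5.40-fold higher with Ad-p73b. The heat shock median was 1.01 with Ad-p53 (5 of 10 higher, percentile 99.9), 1.40 with Ad-p63g (6 higher, percentile 99.9), 0.60 with Ad-p73a (4 higher, percentile 100), 0.81 with Ad-p73b (5 higher, percentile 99.9) and 0.19 with Ad-p63a (0 higher, percentile 98.1), and it was 1.23 between the p63 forms and 0.26 between the p73 forms (percentiles 99.99 and 99.2), with the Ad-p63a value and that between the p73 forms below 0 with spike-in scaling (-0.13 and -0.055) and the Ad-p63a value within the central 95% in 3 of 15 alternatives. EGR2, an immediate early transcription factor, was 112-fold higher with Ad-p53, 109-fold with Ad-p63g, 23.1-fold with Ad-p73b, 12.2-fold with Ad-p73a and 2.10-fold with Ad-p63a, although the immediate early median was below 0 in all 5 infections: -0.19 with Ad-p53, -0.14 with Ad-p63a, -0.40 with Ad-p63g, -0.36 with Ad-p73a and -0.85 with Ad-p73b, the last 2 at percentile 0. With no detection filter the Ad-p73a value was -0.079, within the central 95%, and the Ad-p63a value lay outside it in 3 of 15 alternatives. MYC was 10.6-fold lower with Ad-p53, and FOS 7.71-fold higher with Ad-p63g. Among interferon-induced genes, IFIT3 was higher by 29.8-fold with Ad-p53, 37.8-fold with Ad-p63g and 24.9-fold with Ad-p73b and MX1 by 13.9-fold, 38.5-fold and 10.1-fold, while the list medians (0.48, 0.05, 0.12, -0.0091 and 0.16 in the order Ad-p53, Ad-p63a, Ad-p63g, Ad-p73a, Ad-p73b) lay within the central 95%, the last at 0.011 with members at their bound.

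The NF-kB median was -0.98 with Ad-p53 (6 of 12 lower, 1 higher, percentile 0.440) and -1.09 with Ad-p63g (6 of 11 lower, percentile 0.905), where BIRC3, an inhibitor of apoptosis, was 7.13-fold and the chemokine CXCL1 5.29-fold lower. Both medians moved within the central 95% in 2 of 15 alternatives, the first to -0.23 after normexp and -0.22 with no detection filter, the second to -0.78 with detection on both arrays and 0.084 with no detection filter. The median lay at -0.03 with Ad-p63a, 0.24 with Ad-p73a and -0.48 with Ad-p73b, within the central 95%, but outside it for Ad-p73a in 3 of 15 alternatives (-0.48 with the mean over probes) and for Ad-p73b in 1. In the unfolded protein and integrated stress response, PPP1R15A was 7.28-fold lower with Ad-p53 and 10.3-fold lower with Ad-p63g and DDIT3 5.02-fold and 6.74-fold, with medians of -0.38 with Ad-p53, 0.11 with Ad-p63a, -0.93 with Ad-p63g (percentile 0.100), -0.15 with Ad-p73a and -0.39 with Ad-p73b (percentile 1.07), and the Ad-p73a value lay outside the central 95% in 4 of 15 alternatives and the Ad-p53 value in 1. Cholesterol synthesis medians were -0.59 with Ad-p53 (percentile 1.83), 0.22 with Ad-p63a (percentile 98.4, and -0.096 with spike-in scaling), -0.39 with Ad-p63g (-0.25 with members at their bound), 0.07 with Ad-p73a and 0.07 with Ad-p73b. The Ad-p63a value moved within the central 95% in 5 of 15 alternatives, down to 0.083 after normexp, and the Ad-p53 value in 3, the nearest to 0 being -0.53. Mesenchymal genes had medians of 0.32 with Ad-p53 and 0.03 with Ad-p63a (-0.024 and -0.16 with members at their bound), 0.02 with Ad-p63g, -0.59 with Ad-p73a (0 of 13 past the size rule, percentile 0) and -0.60 with Ad-p73b (percentile 1.71), where THBS1 was 6.77-fold higher. The Ad-p73a value moved within the central 95% with members at their bound (-0.17) and after normexp (-0.13), and the Ad-p63a value was -0.34, outside it, with detection on all 6 arrays. Blood markers lay at 0.25, -0.20, 0.21, -0.15 and 0.17 in the same order of infections, within the central 95%. Lung epithelium markers lay at 0.45 with Ad-p53 (-0.022 with members at their bound), -0.44 with Ad-p63a (0 of 7 past the size rule, percentile 0.160) and -0.10 with Ad-p73a, and endothelium and fibroblast markers at 0.83 with Ad-p63a (percentile 98.9, ACTA2 3.64-fold higher), while only 3 were measured with Ad-p73a and were not ranked. The Ad-p63a value of 0.83 moved within the central 95% in 5 of 13 alternatives, between 0.020 with no detection filter and 0.24 in the authors' table (0.19 with members at their bound).

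Between the p63 forms the medians were -0.04 for interferon, -0.80 for NF-kB, -0.22 for immediate early genes, -0.69 for the unfolded protein response (percentile 1.005), -0.12 for cholesterol synthesis, 0.13 for mesenchymal genes and 0.41 for blood markers. That of NF-kB lay outside the central 95% in 4 of 15 alternatives, and that of the unfolded protein response within it without bright patches (-0.44). Between the p73 forms they were -0.08 for interferon, -0.04 for NF-kB, -0.59 for immediate early genes (percentile 0.0100), -0.38 for the unfolded protein response (percentile 0.550), 0.04 for cholesterol synthesis, -0.19 for mesenchymal genes and 0.17 for blood markers. Values for which no percentile is given lay within the central 95%.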
